A study of Arabidopsis thaliana with 35 samples.

How the data were processed

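Total RNA from dissected hypocotyls, cotyledons and roots of Arabidopsis thaliana seedlings of the natural accession RRS-7 was measured on 35 Affymetrix arrays, each hybridised with biotinylated cRNA. Per the labels' protocols, seedlings grew for 5 days at 20 °C with 16 h of light and 8 h of dark per day under white LEDs at 120 µmol per square metre and second. Plates were then moved to 28 °C at ZT 7 (hours after lights on) of day 5 or stayed at 20 °C, and organs were harvested after 3 h, at ZT 10 of day 5, or after 24 h, at ZT 7 of day 6. The labels call the replicates of a group biological and pooled from material of several harvest sessions. The 12 groups of organ, temperature and time hold 3 arrays each, except root at 28 °C after 3 h, which has 2 arrays here.

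The values used are the deposited log2 RMA values, background-corrected, quantile-normalised and summarised per probe set by the authors; per the labels their tools were RMA and limma, with no versions given, and which arrays were normalised together is not stated. The table holds 22746 probe sets. Values ran from 2.20 to 14.3 and the medians of the arrays from 5.65 to 5.93. Of the probe sets, 13513 name 1 gene in the probe annotation used here, 503 name several genes and 8730 are not listed in it and stay unnamed here. Gene identifiers were matched to the RefSeq annotation of assembly TAIR10.1 for symbols only: 13285 of the 13355 genes tested matched by gene identifier, 70 kept the name of the probe annotation, and 1557 have a symbol other than their locus code. Where a gene had several probe sets (147 genes), the one with the highest mean over all arrays stood for it, and 283 genes rest on a probe set of the _s_at or _x_at type, which can also bind related transcripts.

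The 12 group means were fitted to all 35 arrays in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings, 23 residual degrees of freedom). P-values are those of limma's moderated test, two-sided, adjusted by the Benjamini-Hochberg method within each comparison, and a gene passed at an adjusted p under 0.05. The comparisons were 28 °C against 20 °C in each organ and time, the differences of these temperature effects between organs and between times, the 20 °C arrays of 24 h against those of 3 h, and the organs among the 20 °C arrays. Errors of log2 changes are standard errors from this fit. Correlations of log2 changes are Pearson's r across all genes tested and serve as description, since genes are not independent replicates. Gene numbers expected to be shared by chance are products of the marginal counts.

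Gene lists came in 2 sets. The 26 lists of the first set were written before the data were examined, as were the comparisons, the rule for named genes and the alternatives. The 6 with at least 5 measured genes were tested: Aux/IAA and GH3, expansin and XTH, heat shock, flavonoid, photosynthesis, and reference genes, the last of these not counted among the lists called. A second set of 13 gene families was written after the probe annotation had been seen and before any comparison was looked at, of which 12 had at least 5 measured genes. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the tested lists of 1 set within a comparison, and again with a correlation estimated from the data and with fry. Counts "adjusted over the list alone" adjust gene p-values over the members of that list, not all genes.

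Named genes followed the rule: for each comparison of 28 °C with 20 °C, the 10 largest rises and the 10 largest falls among genes that passed, with every 28 °C array beyond every 20 °C array and a symbol other than the locus code; up to 4 members with the largest change that passed from each list; IAA29, YUC8, PIF4, IAA19 and HSP70-4 whatever their values; and for each difference the 5 most positive and the 5 most negative genes that passed with a symbol. Of those named in advance, only IAA29 is among the named probe sets here. Members that carry only a locus code are given by it, with the name used when the list was written. Not every list member that the rule selects is named in the text.

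The procedure was tested on simulated data in which 200 of 13355 genes were changed. For the comparisons of 28 °C with 20 °C, limma recovered 72% to 86% of changes of 0.5 log2 and 99% to 100% of changes of 1 log2, and 1.68% to 7.57% of its calls were wrong. For the differences between organs and times it recovered 28% to 45% of changes of 0.5 log2 and 90% to 97% of changes of 1 log2, with 1.56% to 7.33% of calls wrong, so most differences of 0.5 log2 were missed there. The number of arrays limits the precision: the median standard error of a log2 change was 0.105, or 0.117 for root at 3 h, and that of a difference 0.149, or 0.158 with root at 3 h. Replicates of a group correlated at r = 0.992 to 0.997 over all 22746 probe sets, and the standard deviation of their difference was 0.166 to 0.266.

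The alternatives tried were a fit of the compared arrays only, eBayes with trend and robust settings, arrayWeights, the replicate number as a block, dim genes left out (5889 genes whose highest group mean was below the median of all values, leaving 7466), centring of each array on the mean of the reference genes, quantile normalisation within each organ, all probe sets in place of 1 per gene, camera with an estimated correlation, fry, Spearman's rho, called genes only for the correlations, and each array left out in turn. A root group at 28 °C and 3 h left with 1 array was assumed to vary like the other groups. No array was left out of the main comparisons.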

Results

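The data are log2 RMA expression values of 35 arrays of hypocotyl, cotyledon and root from Arabidopsis RRS-7 seedlings kept at 20 °C or moved to 28 °C for 3 h or 24 h. Groups have 3 arrays, except root at 28 °C after 3 h with 2. Principal components 1 and 2 held 79.8% and 11% of the variance. The comparisons ask which transcripts respond to warm temperature in each organ, how the organs and times differ, and what changes at 20 °C alone. The largest rises and falls named below are those among genes with a symbol that met the rule for named genes, and larger changes occurred among genes known by a locus code alone. Changes are log2 differences ± standard errors, and n is 3 arrays per group unless stated.

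In the hypocotyl after 3 h at 28 °C, the largest rise among genes with a symbol was that of Hop3 (AT4G12400), a co-chaperone of Hsp70 and Hsp90, which was 3.53-fold higher than at 20 °C (1.82 ± 0.15, limma adjusted p = 8.2e-10). Genes of cell wall proteins went both ways. The expansin-like EXLA1 (1.28 ± 0.14), the expansin EXPA8 (1.15 ± 0.12) and the xyloglucan endotransglucosylase/hydrolase XTH19 (0.93 ± 0.19) rose, and XTH20 (−1.41 ± 0.14) fell. The auxin-conjugating enzyme WES1, also known as GH3.5, rose by 0.94 ± 0.19 and CP5 by 1.08 ± 0.10. The antenna protein gene LHCB4.2 (1.02 ± 0.14), SRC2 (0.93 ± 0.15), SP1L4 (0.88 ± 0.09) and the thionin THI2.2 (0.86 ± 0.17) were also among the 10 largest rises. The largest fall among genes with a symbol was that of the cold-regulated COR27 (−1.55 ± 0.11), and COR15B, a cryoprotective chloroplast protein, changed by −1.33 ± 0.19. The anthocyanin enzyme gene DFR fell by 1.31 ± 0.20. Further falls were those of GSTU25 (−1.48 ± 0.18), SUFE2 (−1.39 ± 0.18), rps16 (−0.98 ± 0.19), OTP81 (−0.84 ± 0.12) and scpl35 (−0.81 ± 0.13). The dehydrin gene LTI30 changed by −1.03 ± 0.27, and by −0.82 without replicate 2 at 28 °C, which ended its call.

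Of the 11 measured heat shock genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with AT5G48570 (ROF2) at 1.85 ± 0.18 and AT5G51440 (HSP23.5) at 1.70 ± 0.18. The list median was 0.60 (camera adjusted p = 5.95e-10, and 0.000354 with an estimated correlation). Of 41 transcripts of cytosolic 40S ribosomal proteins, 30 fell and 0 rose, with a median of −0.40 (adjusted p = 1.02e-24, and 0.0424 with an estimated correlation). AT5G59240 (−0.82 ± 0.16) and AT3G10610 (−0.76 ± 0.10) were among the largest falls of that list. Of 6 flavonoid genes 2 fell (4 adjusted over the list alone), DFR and AT4G14090 (5GT, −1.03 ± 0.17). The list median was −0.39 at an adjusted p of 0.00243, lost at an adjusted p = 0.0765 with an estimated correlation. Of 7 photosynthesis genes 2 rose (3 adjusted over the list alone), LHCB4.2 and LHCB4.3 (0.49 ± 0.11). Its adjusted p was 0.00321, lost at an adjusted p = 0.297 with an estimated correlation. Among 18 expansin and XTH genes 5 rose and 2 fell (5 and 4 adjusted over the list alone), and among 11 Aux/IAA and GH3 genes 3 rose and 0 fell (3 and 0 adjusted over the list alone). Neither of these was called (adjusted p = 0.668 and 0.183). The expansin and XTH median of −0.023 lay opposite in sign to its mean of 0.09 and to the direction of its test. Leaving out any 1 array but replicate 3 at 20 °C took the 3 Aux/IAA and GH3 rises to 1, any 1 array at 20 °C or replicate 1 at 28 °C took the 2 expansin and XTH falls to 1, and without replicate 2 at 28 °C 4 flavonoid genes fell. In the hypocotyl at 3 h, 933 genes were higher and 1021 lower at 28 °C in limma's moderated test, 29 and 20 of them by at least 2-fold. Leaving out replicate 1 at 20 °C gave 1183 genes in place of 1954.

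In the hypocotyl after 24 h at 28 °C, Hop3 was again the largest rise among genes with a symbol (1.86 ± 0.15, limma adjusted p = 6.57e-10). ASPGB1, an asparaginase, rose by 1.21 ± 0.16, WES1 by 1.11 ± 0.19 and BCAT4, an aminotransferase of glucosinolate synthesis, by 0.98 ± 0.09. BZIP34 rose by 0.94 ± 0.09, EXPA8 by 0.93 ± 0.12 and BHLH101, a transcription factor of the iron deficiency response, by 0.93 ± 0.14. The allantoinase gene ALN (0.85 ± 0.12) and BGLU40 (0.83 ± 0.14) also rose. The falls among genes with a symbol were led by LTI30 (−1.87 ± 0.27), GSTU25 (−1.50 ± 0.18), SUFE2 (−1.01 ± 0.18) and XTH20 (−1.0 ± 0.14). They were followed by the cation exchanger CHX16 (−0.96 ± 0.13), the defensin PDF2.5 (−0.89 ± 0.16), COR15B (−0.83 ± 0.19), GSTU22 (−0.83 ± 0.15) and the peroxidase Prx37 (−0.78 ± 0.13). The plastid gene petL (0.87 ± 0.25) and the chitinase gene ChiC (−0.73 ± 0.19) also passed. However, petL lost its call without replicate 2 at 20 °C or replicate 3 at 28 °C (0.42 to 0.73), with only the compared arrays in the fit and with trend and robust eBayes, and ChiC without replicate 1 at 20 °C or replicate 1 or 2 at 28 °C (−0.66 to −0.58).

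In the hypocotyl at 24 h, 7 of the 11 heat shock genes rose and 0 fell (7 and 1 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 1.62e-09, and 0.000473 with an estimated correlation). Of the 40S ribosomal protein transcripts 21 fell and 1 rose. Their median was −0.27 at an adjusted p of 6.28e-16, lost at an adjusted p = 0.196 with an estimated correlation. The member that rose was AT5G39850 (0.59 ± 0.13). Of 54 class III peroxidases 14 fell and 5 rose, with AT4G30170 (−1.18 ± 0.25) and AT3G01190 (−1.15 ± 0.20) falling most. The list median was −0.14 at an adjusted p of 0.00153, lost at an adjusted p = 0.217 with an estimated correlation. Of 47 UDP-glycosyltransferases 7 fell and 2 rose, UGT71C3 (−0.73 ± 0.11) most. The adjusted p of 0.00552 was lost at an adjusted p = 0.39 with an estimated correlation and without replicate 2 at 20 °C (median −0.13). Of 46 plastid-encoded genes 4 rose and 0 fell, among them psbE (0.69 ± 0.12), with a median of 0.15 at an adjusted p of 0.00853. That call was lost at an adjusted p = 0.767 with an estimated correlation, with fry, with dim genes left out, and without replicate 2 at 20 °C or replicate 3 at 28 °C (0.10 to 0.12). In the photosynthesis list 1 of 7 genes rose (1 adjusted over the list alone), LHCB4.3 (0.54 ± 0.11). The adjusted p of 0.017 was lost at an adjusted p = 0.609 with an estimated correlation, with fry and with dim genes left out. Of the iron deficiency genes, the peptide gene AT1G47400 (IMA1) rose by 1.08 ± 0.11 and PYE, a basic helix-loop-helix regulator, by 0.62 ± 0.10. In the same list AT3G13610 (F6H1), an enzyme of coumarin synthesis, changed by −0.94 ± 0.17. Aux/IAA and GH3 genes (1 up, 0 down, and 1 and 0 adjusted over the list alone), expansin and XTH genes (3 up, 2 down, and 4 and 2 adjusted over the list alone) and flavonoid genes (0 in either direction on both counts) were not called. The expansin and XTH median (−0.020) and mean (0.015) differed in sign. The 21 falls of the 40S list became 12 and 13 without replicate 1 or 3 at 20 °C and 13 without replicate 1 at 28 °C. The 4 rises of plastid-encoded genes became 2 without replicate 2 at 20 °C, and the 2 expansin and XTH falls 1 without replicate 1 or 3 at 20 °C or replicate 2 at 28 °C. For the UDP-glycosyltransferases 4 fell without replicate 2 at 28 °C, and the 2 rises became 1 without replicate 1 at 28 °C and 0 without any other array but replicate 2 at 20 °C. In all, 679 genes were higher and 612 lower in limma's moderated test, 21 and 18 by at least 2-fold. The count of 1291 became 827 without replicate 1 at 20 °C and 746 without replicate 2 at 28 °C.

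In the cotyledon after 3 h at 28 °C, the largest rises among genes with a symbol were those of EXO (1.69 ± 0.10, limma adjusted p = 5.04e-14), Hop3 (1.66 ± 0.15), the acireductone dioxygenase ARD4 (1.63 ± 0.09), and BGLU40 (1.53 ± 0.14). The methionine sulfoxide reductase MSRB5 (1.51 ± 0.13), CP5 (1.45 ± 0.10), the lectin JAL34 (1.41 ± 0.08) and EXPA8 (1.25 ± 0.12) followed. IAGLU, a glucosyltransferase that conjugates auxin, rose by 1.23 ± 0.15 and NET3A by 1.19 ± 0.11. Among the falls of genes with a symbol, the cold-regulated COR27 fell by 1.76 ± 0.11, with COR15B at −1.63 ± 0.19 and COR15A at −1.51 ± 0.14. NRPA1, the largest subunit of RNA polymerase I, which transcribes the ribosomal RNA genes, fell by 1.45 ± 0.11. RBL (−1.35 ± 0.12), CHX16 (−1.28 ± 0.13), scpl35 (−1.21 ± 0.13), CIL (−1.21 ± 0.11), the vacuolar sugar transporter TMT1 (−1.20 ± 0.10) and 2A6 (−1.18 ± 0.11) completed the 10 largest falls.

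Of the 41 transcripts of 40S ribosomal proteins, 31 fell and 0 rose in the cotyledon at 3 h, with AT3G57490 (−1.30 ± 0.14) and AT5G15520 (−1.06 ± 0.13) lowest. The median was −0.48 at a camera adjusted p of 7.8e-20, lost at an adjusted p = 0.0965 with an estimated correlation. Heat shock genes rose in 7 of 11 cases and fell in 0 (7 and 0 adjusted over the list alone), with AT1G53540 (HSP17.6C) at 3.00 ± 0.19. Their median was 0.50 (adjusted p = 1.97e-06, and 0.00464 with an estimated correlation). In the mitosis list both measured genes, the Aurora kinases AUR1 (1.02 ± 0.16) and AUR2 (1.09 ± 0.18), rose, and in the DNA replication list both measured genes, PRL (−0.77 ± 0.13) and ICU2 (−0.91 ± 0.14), fell. The response regulator RR16 of the cytokinin list fell by 0.91 ± 0.13. Of the auxin lists, Aux/IAA and GH3 had 3 genes up and 1 down (3 and 1 adjusted over the list alone), with WES1 at 0.86 ± 0.19, and AT2G18010 (SAUR10) rose by 0.72 ± 0.11. Expansin and XTH genes went both ways, 4 up and 3 down (4 and 3 adjusted over the list alone), with XTH18 at 0.97 ± 0.14 and EXPA9 at −0.67 ± 0.14. Neither of these lists was called (adjusted p = 0.39 each). The flavonoid (0 up and 0 down on both counts) and photosynthesis (1 up and 0 down on both counts) lists were not called either. Without replicate 3 of either temperature 0 Aux/IAA and GH3 genes fell, and without replicate 3 at 28 °C 1 flavonoid gene did. Of the jacalin-related lectins, too few for a test with 4 measured, JAL34, JAL33 (0.82 ± 0.08) and JAL22 (0.63 ± 0.11) rose. In the cotyledon at 3 h 1375 genes were higher and 1610 lower in limma's moderated test, 100 and 125 by at least 2-fold. The split became 1829 and 1199 with the arrays centred on the reference genes.

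In the cotyledon after 24 h at 28 °C, genes of the iron deficiency response were among the largest rises of genes with a symbol: BHLH101 by 2.61 ± 0.14 and PYE by 2.12 ± 0.10 (limma adjusted p = 5.84e-16 and 1.04e-16), together with the peptide gene AT1G47400 (IMA1, 2.97 ± 0.11). The fourth measured gene of that list, AT3G13610 (F6H1), was lower (−0.56 ± 0.17), without a call when replicate 1 at 20 °C or replicate 3 at 28 °C was left out (−0.49 to −0.42). Hop3 rose by 2.85 ± 0.15, BCAT4 by 2.13 ± 0.09, ASPGB1 by 2.04 ± 0.16, BGLU40 by 1.88 ± 0.14 and PPDK, pyruvate orthophosphate dikinase, by 1.79 ± 0.11. PCME (1.43 ± 0.12), the ubiquitin ligase PUB19 (1.38 ± 0.17) and the jasmonate methyltransferase JMT (1.36 ± 0.10) followed. The cold response genes LTI30 (−2.66 ± 0.27), COR15B (−2.52 ± 0.19) and COR15A (−2.15 ± 0.14) had the largest falls among genes with a symbol. They were followed by CHX16 (−1.90 ± 0.13), PORB, an enzyme of chlorophyll synthesis (−1.84 ± 0.20), scpl35 (−1.78 ± 0.13), BGLU44 (−1.65 ± 0.13), ChiC (−1.45 ± 0.19) and the plastid genes rpl20 (−1.46 ± 0.28) and ycf3 (−1.42 ± 0.22).

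In the cotyledon at 24 h, 10 of the 11 heat shock genes rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 2.12 (camera adjusted p = 2.94e-13, and 4.83e-05 with an estimated correlation). AT1G53540 (HSP17.6C) and AT5G48570 (ROF2) each rose by 3.38, with standard errors of 0.19 and 0.18. Of the plastid-encoded genes 18 fell and 2 rose, among them accD (−1.16 ± 0.21). The median was −0.41 at an adjusted p of 0.00282, lost at an adjusted p = 0.495 with an estimated correlation. The flavonoid list had 4 of 6 genes up and 0 down (4 and 0 adjusted over the list alone), with DFR at 1.09 ± 0.20 and UGT78D1 at 0.56 ± 0.16. The median was 0.46 at an adjusted p of 0.0492. That call was lost at an adjusted p = 0.302 with an estimated correlation, with dim genes left out and under both other scalings, and without replicate 1 or 3 of either temperature (medians 0.38 to 0.45). The 40S ribosomal protein transcripts, lower at 3 h, had 8 members up and 0 down at 24 h with a median of 0.071 (adjusted p = 0.13). AT5G39850 among them rose by 1.72 ± 0.13. The clock gene GI changed by −1.27 ± 0.07 and RR16 by −0.86 ± 0.13, and EXPB1 fell by 1.2 ± 0.15. IAA29 rose by 0.53 ± 0.15, and had no call without replicate 1 at 28 °C (0.36). Aux/IAA and GH3 (2 up and 0 down, 1 and 0 adjusted over the list alone, median −0.058 against a mean of 0.069), expansin and XTH (2 up and 3 down on both counts) and photosynthesis (1 up and 0 down on both counts, median −0.010 against a mean of 0.036) were not called. The 4 flavonoid rises became 2 without replicate 1 or 3 at 20 °C or replicate 1 at 28 °C. The 18 falls of plastid-encoded genes became 11 without replicate 3 at 20 °C and 10 without replicate 2 at 28 °C, and the 8 rises of the 40S list 5 without replicate 3 at 20 °C and 4 without replicate 3 at 28 °C, with 1 fall without replicate 2 at 20 °C. The 2 Aux/IAA and GH3 rises became 1 without replicate 1 at 20 °C or replicate 1 or 3 at 28 °C, with 1 fall without replicate 2 at 20 °C, and the 2 expansin and XTH rises became 1 without replicate 1 or 3 at 20 °C. Limma's moderated test found 2009 genes higher and 1796 lower at 24 h, 165 and 166 by at least 2-fold. With centring on the reference genes the split was 2647 and 1126.

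In the root after 3 h at 28 °C, with 2 arrays against 3, the largest rise among genes with a symbol was that of Hop3 (3.64 ± 0.17, limma adjusted p = 1.44e-16). Other rises were those of the plastid chaperonin Cpn60beta2 (1.61 ± 0.11), the co-chaperone SGT1A (1.32 ± 0.13) and the Hsp70 exchange factor Fes1A (1.26 ± 0.14). Hsp70-2 rose by 1.18 ± 0.11, ATERDJ3B, a J-protein of the endoplasmic reticulum, by 1.18 ± 0.11 and HSA32 by 1.15 ± 0.13. EXLA1 (1.09 ± 0.16) was among them too. WRKY53 rose by 1.26 ± 0.26 but had no call without replicate 2 at 28 °C (0.93), and AR781 (1.06 ± 0.33) lost its call without either array at 28 °C and without replicate 1 or 2 at 20 °C (0.72 to 1.12), and with trend and robust eBayes. The largest falls among genes with a symbol were those of the mitochondrial NAD(P)H dehydrogenase NDB4 (−1.99 ± 0.18), GSTU25 (−1.57 ± 0.20), XTH20 (−1.39 ± 0.15), LTI30 (−1.38 ± 0.30) and CYP71B22 (−1.35 ± 0.15). They were followed by GSTU22 (−1.31 ± 0.16), scpl40 (−1.26 ± 0.14), UGT73B4 (−1.18 ± 0.20), COR27 (−1.16 ± 0.13) and LPR1 (−1.13 ± 0.17).

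In the root at 3 h, 10 of the 11 heat shock genes rose and 0 fell (10 and 0 adjusted over the list alone), led by AT5G48570 (ROF2, 5.26 ± 0.21), AT2G29500 (HSP17.6B, 4.76 ± 0.26) and AT1G53540 (HSP17.6C, 4.54 ± 0.21). The median was 1.26 and the mean 2.39 (camera adjusted p = 1.45e-32, and 2.42e-08 with an estimated correlation). The 40S ribosomal protein transcripts were not called (1 up, 1 down, median 0.040, adjusted p = 0.567). Of 7 photosynthesis genes 4 rose and 0 fell (6 and 0 adjusted over the list alone), PSAN most (0.79 ± 0.18). The median was 0.47 at an adjusted p of 0.000101, lost at an adjusted p = 0.184 with an estimated correlation. Without replicate 2 at 28 °C the photosynthesis median was 0.035 with no call and 0 of the 7 genes passed, PSAN at 0.26, LHCB4.2 at 0.34, LHCB4.1 at 0.24 and PSBY at −0.042 among them. Without replicate 2 at 20 °C 2 passed, and with only the compared arrays in the fit none of these 4 had a call. Of the other organ markers, the root hair gene EXPA7 rose by 0.59 ± 0.16 (no call without replicate 1 at 28 °C or at 20 °C, 0.49 to 0.51). The stomatal genes SPCH (−0.20 ± 0.20), MUTE (0.18 ± 0.12) and FMA (−0.14 ± 0.14) and the shoot apex genes CLV3 (−0.006 ± 0.12) and LAS (−0.088 ± 0.13) did not pass. Of 46 plastid-encoded genes 4 rose and 0 fell. Here 5 families passed with small medians at an adjusted p of 0.0179 each. All of these calls were lost with an estimated correlation, at an adjusted p = 0.231 for the UDP-glycosyltransferases and 0.208 for the others. They were class III peroxidases (2 up, 11 down, median −0.14, Prx37 at −0.97 ± 0.14), UDP-glycosyltransferases (0 up, 7 down, −0.11), and SWEET sugar transporters (0 up, 4 down, −0.10, SWEET16 at −0.87 ± 0.14). The others were tubulins (0 up, 2 down, −0.20) and mitochondrial-encoded genes (1 up, 0 down, 0.15, cox2 at 0.76 ± 0.16). Single arrays ended 4 of these calls: replicate 1 at 28 °C for the UDP-glycosyltransferases (median −0.046) and the SWEET list (−0.036), replicate 2 at 28 °C for the tubulins (−0.18), and replicate 2 at 28 °C or replicate 1 at 20 °C for the mitochondrial genes (0.11 each). The lists Aux/IAA and GH3 (0 up and 0 down on both counts), expansin and XTH (1 up and 3 down, 2 and 4 adjusted over the list alone) and flavonoid (0 up and 1 down on both counts, HYH at −0.82 ± 0.14) were not called. The counts of members moved too. Without replicate 2 at 28 °C 7 peroxidases and 4 UDP-glycosyltransferases fell, and without replicate 1 at 20 °C 1 of the latter rose. The SWEET falls became 2 without either array at 28 °C, and the tubulin falls 0 without replicate 2 at 28 °C and 1 without any other array. The mitochondrial rises became 2 without replicate 2 or 3 at 20 °C, and 1 Aux/IAA and GH3 gene rose without replicate 3 at 20 °C. Expansin and XTH counts up and down became 0 and 3, and 2 and 1, without replicates 1 and 2 at 28 °C, and 0 and 4, and 2 and 1, without replicates 1 and 3 at 20 °C. For the 40S list they became 0 and 1, and 1 and 0, without replicates 1 and 2 at 28 °C, and 0 and 0 without replicate 3 at 20 °C. In limma's moderated test 719 genes were higher and 715 lower, 57 and 59 by at least 2-fold. The count of 1434 became 731 without replicate 2 and 857 without replicate 1 at 28 °C. Centring on the reference genes made the split 527 and 857.

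In the root after 24 h at 28 °C, Hop3 rose by 3.26 ± 0.15 (limma adjusted p = 4.01e-17) and the transcription factor gene WRKY53 by 2.40 ± 0.23. DLAH, a lipase, rose by 1.76 ± 0.21, the sucrose transporter gene SWEET11 by 1.70 ± 0.14 and AR781 by 1.69 ± 0.29. Further rises were those of the calmodulin-like CML37 (1.68 ± 0.19), SGT1A (1.51 ± 0.11), Hsp70-2 (1.32 ± 0.10) and Cpn60beta2 (1.25 ± 0.10). The zinc finger gene STZ rose by 1.48 ± 0.41 but had no call without replicate 1 at 20 °C (1.19). The largest falls among genes with a symbol were LTI30 (−2.34 ± 0.27), NDB4 (−2.06 ± 0.16), the beta-expansin EXPB2 (−1.83 ± 0.24), GSTU25 (−1.68 ± 0.18) and UGT73B4 (−1.45 ± 0.18). They were followed by scpl31 (−1.29 ± 0.12), CYP71B22 (−1.28 ± 0.13), OCT1 (−1.2 ± 0.24), XTH26 (−1.19 ± 0.13) and scpl40 (−1.06 ± 0.12). GRX480, a glutaredoxin of the salicylic acid list, rose by 0.98 ± 0.17.

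In the root at 24 h, 10 of the 11 heat shock genes rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 1.14 (camera adjusted p = 2.56e-20, and 1.66e-06 with an estimated correlation). Of the 40S ribosomal protein transcripts 20 fell and 1 rose, with AT5G15520 at −0.76 ± 0.13 and AT5G39850 at 0.98 ± 0.13. Their median was −0.22 at an adjusted p of 7.49e-08, lost at an adjusted p = 0.601 with an estimated correlation. Of the photosynthesis genes 3 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.35 at an adjusted p of 0.0358. That call was lost at an adjusted p = 0.491 with an estimated correlation, with fry, with dim genes left out and with centring on the reference genes, and without replicate 1 at 28 °C (0.33) or replicate 3 at 20 °C (0.14). Expansin and XTH genes had 5 up and 3 down (5 and 3 adjusted over the list alone), with XTH21 at 1.01 ± 0.18 and EXPA8 at 0.98 ± 0.12. Aux/IAA and GH3 genes had 3 up and 0 down (3 and 0 adjusted over the list alone), with IAA18 at 0.78 ± 0.09, and flavonoid genes 2 up and 0 down (2 and 0 adjusted over the list alone), with UGT78D1 at 1.01 ± 0.16. None of these lists was called (adjusted p = 0.369, 0.0612 and 0.553). The flavonoid median of −0.15 lay opposite in sign to its mean of 0.10. The 20 falls of the 40S list became 10 without replicate 2 at 28 °C or replicate 1 at 20 °C and 13 without replicate 2 at 20 °C. The 3 photosynthesis rises became 1 without replicate 3 at 20 °C, and the 5 expansin and XTH rises 3 without replicate 1 at 28 °C or replicate 2 at 20 °C. In limma's moderated test 1120 genes were higher and 1244 lower, 102 and 71 by at least 2-fold.

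Several lists had fewer than 5 measured genes or were never called. IAA29, named in advance, changed by 0.28 ± 0.15 and 0.18 ± 0.15 in the hypocotyl, 0.31 ± 0.15 in the cotyledon at 3 h, and 0.13 ± 0.16 and 0.15 ± 0.15 in the root, at 3 h and 24 h in turn, without passing. In the cotyledon at 3 h it passed when replicate 3 at 20 °C was left out (0.44). The shade response gene HAT2 rose in the hypocotyl (0.53 ± 0.09 and 0.66 ± 0.09) and in the cotyledon at 24 h (0.41 ± 0.09), and FHL of the same list passed in no comparison. The auxin biosynthesis genes YUC2, YUC4, YUC6 and YUC11 did not pass in any of the 6 comparisons, with log2 changes between −0.23 and 0.27. Of the auxin transport and brassinosteroid lists, no member is measured under a name here. In the endoplasmic reticulum folding list ATERDJ3B rose in all 6 comparisons (0.58 to 1.18), the calreticulin CRT1b rose in all 3 organs at 3 h, and BZIP28 in all comparisons but hypocotyl at 24 h. CRT1b changed by 0.39 ± 0.11 in hypocotyl (0.37 with no call without replicate 1 or 2 at 20 °C), 0.83 ± 0.11 in cotyledon and 0.53 ± 0.12 in root (0.50 with no call without replicate 2 at 28 °C). BZIP28 changed by 0.38 ± 0.10 and 0.24 ± 0.10 in hypocotyl at 3 h and 24 h, 0.48 ± 0.10 and 0.44 ± 0.10 in cotyledon, and 0.35 ± 0.11 and 0.42 ± 0.10 in root. In root at 3 h it had no call without any 1 of the 5 arrays (0.34 to 0.37) or with centring on the reference genes. BZIP60 of that list rose in the cotyledon at 24 h (0.39 ± 0.11). Of the gibberellin receptors, GID1A (−0.28 ± 0.10) and GID1B (0.37 ± 0.13) passed in the cotyledon at 24 h. Both lost the call without replicate 1 or 3 at 20 °C or replicate 1 at 28 °C, GID1A also without replicate 3 and GID1B without replicate 2 at 28 °C (−0.27 to −0.23 and 0.31 to 0.35). GID1A also lost it with only the compared arrays in the fit, with arrayWeights and with centring on the reference genes. GID1C of the same list passed in no comparison of 28 °C with 20 °C. The ethylene gene EIN3 passed in the cotyledon at 3 h (0.26 ± 0.08; 0.19 with no call without replicate 3 at 20 °C, and none with only the compared arrays in the fit or with arrayWeights) and ARL in the cotyledon at 24 h (−0.66 ± 0.13). The flowering gene SMZ changed by −0.53 ± 0.12 in the root at 3 h (−0.44 with no call without replicate 2 at 28 °C) and by −0.37 ± 0.11 in the cotyledon at 24 h (−0.31 to −0.30 with no call without replicate 2 of either temperature). SNZ of that list changed by 0.37 ± 0.11 in the hypocotyl at 24 h, with no call without replicate 1 at 20 °C or replicate 2 or 3 at 28 °C (0.29 to 0.38). The families that limma's camera test called in no comparison of 28 °C with 20 °C were the glutathione S-transferases (GSTU25 down in hypocotyl and root), CYP71B cytochromes, beta-glucosidases (BGLU40 up in hypocotyl and cotyledon), serine carboxypeptidase-like proteins (scpl35 down in all 6 comparisons) and TBL proteins (TBL26 at 1.35 ± 0.13 in the cotyledon at 24 h). Of the 8 reference genes, AT2G32170 rose (0.22 ± 0.08) and AT5G46630 changed by −0.27 ± 0.08 in the cotyledon at 24 h, and PEX4 by −0.26 ± 0.07 in the root at 24 h. The counts adjusted over the list alone were the same. AT2G32170 lost its call without any 1 of the 20 °C arrays or replicate 3 at 28 °C (0.16 to 0.23), with only the compared arrays in the fit, with arrayWeights and with quantile normalisation within organs, and PEX4 without replicate 2 at 28 °C or replicate 1 at 20 °C (−0.24 to −0.22). AT5G46630 had no call with centring on these genes. The reference list was called in no comparison of 28 °C with 20 °C.

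Further members of the lists with fewer than 5 measured genes passed at 28 °C against 20 °C. Of the stomatal genes, SPCH changed by −0.56 ± 0.18 in the hypocotyl at 3 h (no call without replicate 1 or 2 at 20 °C or replicate 1 or 3 at 28 °C, −0.57 to −0.48). In the cotyledon at 24 h MUTE changed by −0.42 ± 0.11 (−0.30 with no call without replicate 1 at 20 °C) and FMA by −0.34 ± 0.12. FMA had no call without replicate 2 or 3 of either temperature (−0.35 to −0.30), with arrayWeights or with centring on the reference genes. In the root at 24 h EXPA7 rose by 0.46 ± 0.15 (no call without replicate 1 at 28 °C or replicate 1 or 2 at 20 °C, 0.35 to 0.45), and of the root markers PYK10 by 0.41 ± 0.09 and AT5G47950 by 0.44 ± 0.15. AT5G47950 had no call without any 1 array but replicate 3 at 20 °C (0.38 to 0.49). PYK10 also rose in the cotyledon at 3 h, by 0.29 ± 0.09, with no call without replicate 2 at 20 °C or replicate 1 or 2 at 28 °C (0.20 to 0.28), with only the compared arrays in the fit or with arrayWeights. The Aurora kinase AUR2 rose by 1.1 ± 0.18 in the cotyledon at 24 h and AUR1 by 0.48 ± 0.16, which had no call without replicate 3 of either temperature (0.20 to 0.36), with only the compared arrays in the fit or with quantile normalisation within organs. ICU2 rose by 0.54 ± 0.14 in the cotyledon at 24 h and changed by −0.47 ± 0.14 in the hypocotyl at 3 h, with no call there without replicate 1 or 2 at 20 °C or replicate 1 at 28 °C (−0.47 to −0.22) or with only the compared arrays in the fit. The clock gene GI rose by 0.33 ± 0.07 in the cotyledon and 0.26 ± 0.07 in the hypocotyl at 3 h and changed by −0.44 ± 0.07 in the hypocotyl at 24 h. In the hypocotyl at 3 h it had no call without replicate 1 of either temperature (0.18 to 0.24) or with only the compared arrays in the fit. AT5G52660 of the clock list rose by 0.46 ± 0.10 in the cotyledon at 3 h. COR47 changed by −0.47 ± 0.10 in the hypocotyl at 24 h and by −0.61 ± 0.10 and −0.71 ± 0.10 in the cotyledon at 3 h and 24 h, and COR15A by −0.72 ± 0.14 and −0.55 ± 0.14 in the hypocotyl. Of the iron deficiency genes, AT1G47400 rose by 0.62 ± 0.11 in the cotyledon at 3 h and by 0.82 ± 0.13 and 1.14 ± 0.11 in the root at 3 h and 24 h, and PYE by 0.49 ± 0.10 in the cotyledon at 3 h. BHLH101 rose by 0.58 ± 0.14 in the root at 24 h, by 0.52 ± 0.14 in the hypocotyl at 3 h (no call without replicate 1 or 3 at 20 °C or replicate 3 at 28 °C, 0.41 to 0.42) and by 0.41 ± 0.14 in the cotyledon at 3 h. The last had no call without replicate 1 or 3 of either temperature (0.36 to 0.38) or with arrayWeights. GRX480 rose by 0.97 ± 0.18 in the root at 3 h. In the cotyledon WRKY53 rose by 0.69 ± 0.23 at 24 h and SAG101 changed by −0.49 ± 0.12 at 3 h and −0.39 ± 0.12 at 24 h. At 24 h both had no call without replicate 1 or 3 at 20 °C or replicate 1 at 28 °C (0.40 to 0.67 and −0.35 to −0.25) or with only the compared arrays in the fit. AT2G18010 rose in the hypocotyl by 0.44 ± 0.11 at 3 h (0.34 with no call without replicate 2 at 28 °C) and by 0.45 ± 0.11 at 24 h (no call without replicate 1 at 20 °C or replicate 1 or 2 at 28 °C, 0.34 to 0.40). ARR15 of the cytokinin list changed by −0.56 ± 0.14 in the hypocotyl at 24 h (−0.47 with no call without replicate 2 at 20 °C).

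The responses were compared between organs through the genes that passed in each. After 3 h, 171 genes rose and 159 fell in all 3 organs, after 24 h 168 and 123, and in all 6 comparisons 60 rose and 37 fell. Hop3 (mean change 2.51), AT5G51440 (HSP23.5, 2.54), AT5G48570 (ROF2, 2.98), Cpn60beta2 (0.99), ATERDJ3B (0.82), CP5 (0.81), HSA32 (0.71) and PGRL1B (0.71) were among those that rose, and 2A6 (−0.92), scpl35 (−0.91), ASPGA1 (−0.68) and ATMPK8 (−0.59) among those that fell. Hypocotyl and cotyledon at 3 h shared 529 genes up and 699 down where 96.1 and 123 were expected by chance, with 13 in opposite directions against 218 expected. Across genes, the changes at 3 h correlated at r = 0.638 between hypocotyl and cotyledon, 0.339 between root and cotyledon and 0.393 between root and hypocotyl. At 24 h these values were 0.492, 0.257 and 0.355. Between 3 h and 24 h in the same organ r was 0.482 in hypocotyl, 0.376 in cotyledon and 0.592 in root. In the root, 367 genes were up and 373 down at both times against 60.3 and 66.6 expected. In the cotyledon, 670 genes were up and 607 down at both times and 389 turned direction, against 427 expected by chance.

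**Figure D1:**
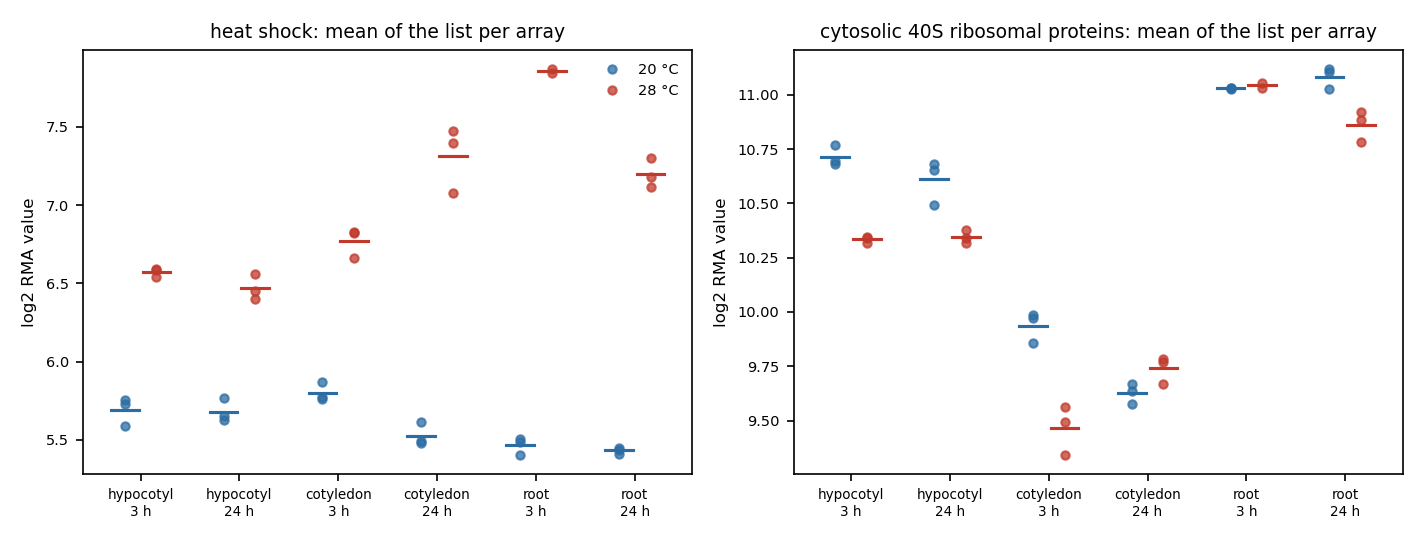
Mean log2 RMA value of the 11 heat shock genes and of the 41 transcripts of 40S ribosomal proteins (y axis) in each array, by organ and hours at the temperature (x axis): points are arrays, bars are group means, blue is 20 °C and red 28 °C. Heat shock means at 28 °C lay above those at 20 °C in each organ and time, 7.86 against 5.47 in root at 3 h, and the 40S means in the cotyledon at 3 h were 9.47 at 28 °C against 9.94 at 20 °C.

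After 3 h, the root response was higher than that of the cotyledon for Hop3 by 1.98 ± 0.23 and for Fes1A by 1.42 ± 0.19 (limma adjusted p = 2.62e-07 and 3.2e-06). STR18 (1.34 ± 0.23), COR15B (1.31 ± 0.28) and CIL (1.3 ± 0.17) followed. The root response was lower for NDB4 (−2.47 ± 0.24), EXO (−1.87 ± 0.15), SWEET16 (−1.75 ± 0.19), MSRB6 (−1.69 ± 0.15) and IAGLU (−1.52 ± 0.22). Heat shock genes responded more in root, 10 of 11 higher and 1 lower (10 and 1 adjusted over the list alone; median 1.3, camera adjusted p = 1.33e-13, and 4e-05 with an estimated correlation). For the 40S list 25 of 41 differences were higher in root and 0 lower (median 0.46, adjusted p = 4.67e-20, lost at an adjusted p = 0.0623 with an estimated correlation). Expansin and XTH differences were 2 up and 7 down (3 and 7 adjusted over the list alone; adjusted p = 0.0482, lost at an adjusted p = 0.377 with an estimated correlation). The 1 lower heat shock difference had no call without replicate 2 or 3 at 20 °C or 1 or 2 at 28 °C of cotyledon, or without replicate 1 or 2 at 28 °C or 1 at 20 °C of root. Without replicate 1 of root at 28 °C 15 differences of the 40S list were higher, and without replicate 2 the expansin and XTH counts were 1 up and 5 down. Against the hypocotyl, the root response was higher for Hop3 (1.82 ± 0.23), Cpn60beta2 (1.28 ± 0.15), SUFE2 (1.2 ± 0.27) and Fes1A (1.15 ± 0.19). It was lower there for NDB4 (−1.79 ± 0.24), CYP71B22 (−1.39 ± 0.20), EXLA2 (−1.34 ± 0.19), MSRB6 (−1.27 ± 0.15) and scpl40 (−1.22 ± 0.18). GH9B8 (1.16 ± 0.32) lost its call in 7 of the 11 leave-outs (1.01 to 1.22) and with trend and robust eBayes. Between hypocotyl and cotyledon, TMT1 (0.89 ± 0.14), scpl20 (0.88 ± 0.12) and RR16 (0.79 ± 0.18) had the higher response in hypocotyl. AUR2 (−1.42 ± 0.26), GSTU25 (−1.26 ± 0.25), MSRB5 (−1.17 ± 0.18), SUFE2 (−1.11 ± 0.25) and JAL34 (−1.06 ± 0.11) had the lower. ChiC (1.02 ± 0.27) and STR18 (0.80 ± 0.21) also passed there, losing the call in 7 and 5 of 12 leave-outs (0.846 to 0.995 and 0.65 to 0.79). With only the compared arrays in the fit both lost it, as did ChiC with trend and robust eBayes and STR18 with centring on the reference genes. Some of these genes lay below the median of all values (5.80) at 20 °C in the organ without the fall: COR15B (4.46) and CIL (3.46) in root, NDB4 in hypocotyl (4.84), CYP71B22 and scpl40 in hypocotyl (4.86 and 3.69), and GSTU25 and SUFE2 in cotyledon (4.67 and 3.85). NDB4 lay at 4.81 at 20 °C and 5.29 at 28 °C in cotyledon. No background level was measured, so whether a low level limited a fall in these organs stays open. The counts in limma's moderated test, higher and lower, were 869 and 664 for root minus cotyledon, 346 and 362 for root minus hypocotyl and 244 and 204 for hypocotyl minus cotyledon. The last count, 448, became 242 with only the compared arrays in the fit. The root minus hypocotyl count, 708, became 394 and 444 without replicate 2 or 1 of root at 28 °C. Centring on the reference genes made the splits 529 and 1032, 218 and 453, and 144 and 255, and moved the median of all genes for root minus cotyledon to −0.10.

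After 24 h, the hypocotyl response was lower than that of the cotyledon for BHLH101 (−1.68 ± 0.19, limma adjusted p = 1.94e-07), PPDK (−1.64 ± 0.16), PYE (−1.50 ± 0.15), PUB19 (−1.40 ± 0.24) and the metallothionein MT1C (−1.39 ± 0.20). It was higher for COR15B (1.69 ± 0.26), COR15A (1.60 ± 0.19), PORB (1.41 ± 0.28), ndhE (1.36 ± 0.33) and rpl20 (1.47 ± 0.39, no call with only the compared arrays in the fit). Root minus cotyledon was 2.62 ± 0.26 for COR15B, 2.46 ± 0.19 for COR15A, 2.05 ± 0.28 for PORB and 2.06 ± 0.18 for BGLU44. These genes lay at 4.36, 3.12, 5.38 and 5.16 in root at 20 °C, below the median of all values of 5.80, and whether that limited a fall there was not tested. COR15B, COR15A and PORB did not pass in root, while BGLU44 rose in root by 0.42 ± 0.13 (0.37 and 0.27 with no call without replicate 1 at 28 °C or replicate 3 at 20 °C). The root response was lower than that of the cotyledon for PPDK (−2.45 ± 0.16), PYE (−2.31 ± 0.15), BHLH101 (−2.04 ± 0.19), ASPGB1 (−2.20 ± 0.23) and EXPB2 (−1.83 ± 0.35), and higher for SWEET11 (1.96 ± 0.20). The root response was higher than that of the hypocotyl for SWEET11 (1.93 ± 0.20), WRKY53 (1.78 ± 0.33), CML37 (1.58 ± 0.27), DLAH (1.54 ± 0.29) and SUFE2 (1.52 ± 0.25). Its response was lower than in hypocotyl for NDB4 (−1.92 ± 0.22), EXPB2 (−1.55 ± 0.35), ASPGB1 (−1.37 ± 0.23), BZIP61 (−1.31 ± 0.16) and CYP71B22 (−1.26 ± 0.19). Of those that fell in root, NDB4, EXPB2 and CYP71B22 lay low in hypocotyl at 20 °C (4.85, 4.70 and 4.77), as did EXPB2 in cotyledon (4.71). The heat shock list responded less in hypocotyl than in cotyledon (median −0.995, 0 up and 7 down, 0 and 8 adjusted over the list alone; camera adjusted p = 3.14e-08, and 0.00116 with an estimated correlation). It responded more in root than in hypocotyl (0.78, 9 up and 0 down, 9 and 1 adjusted over the list alone; 5.39e-11 and 0.000182). Without replicate 3 of hypocotyl at 28 °C or of root at 20 °C the last counts were 8 up and 1 down. For root minus cotyledon it was not called (3 up and 2 down on both counts, adjusted p = 0.744), with a median of 0.11 and a mean of −0.022. In limma's moderated test the counts higher and lower were 675 and 937 for hypocotyl minus cotyledon (476 and 1172 centred on the reference genes), 1203 and 1479 for root minus cotyledon, and 491 and 508 for root minus hypocotyl.

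The temperature effect differed between 24 h and 3 h for the most genes in the cotyledon (2185, limma). In the cotyledon NRPA1 and NRPA2, both subunits of RNA polymerase I, changed by −1.45 ± 0.11 and −1.15 ± 0.09 at 3 h and by 0.81 ± 0.11 and 1.0 ± 0.09 at 24 h. The differences were 2.26 ± 0.15 and 2.15 ± 0.13 (limma adjusted p = 1.26e-12 and 1.04e-13). In the 20 °C arrays alone, NRPA1 changed by −1.38 ± 0.11 and NRPA2 by −1.39 ± 0.09 from the harvest at 3 h to that at 24 h. BHLH101 (2.21 ± 0.19), CIL (2.06 ± 0.16) and JMT (2.01 ± 0.14) followed. The most negative differences among genes with a symbol were those of LTI30 (−1.97 ± 0.38), GI (−1.60 ± 0.10), PORB (−1.54 ± 0.28), CCL (−1.54 ± 0.20) and BGLU44 (−1.53 ± 0.18). In the cotyledon, 32 of the 41 40S ribosomal protein transcripts had a higher effect at 24 h and 0 a lower (median 0.50, camera adjusted p = 1.08e-20, lost at an adjusted p = 0.0832 with an estimated correlation). The heat shock list was higher at 24 h in the cotyledon (median 0.60, 6 up and 0 down, 7 and 0 adjusted over the list alone; adjusted p = 2.74e-05, and 0.0123 with an estimated correlation). It was lower in the root (median −0.38, 0 up and 2 down, 0 and 5 adjusted over the list alone; 4.11e-05 and 0.0144). In the root the most positive differences among genes with a symbol were those of SWEET11 (1.48 ± 0.21), COR27 (1.13 ± 0.17), CYP71B37 (1.07 ± 0.19), SWEET14 (1.05 ± 0.20) and the terpene synthase TPS-CIN (1.01 ± 0.16). The most negative were those of scpl31 (−2.01 ± 0.18), petA (−1.11 ± 0.25), FACT (−1.04 ± 0.22), ATSBT5.2 (−0.997 ± 0.133) and ndhD (−0.98 ± 0.19). In the hypocotyl DFR (1.53 ± 0.29), ATMPK13 (0.86 ± 0.17) and COR27 (0.85 ± 0.16) were higher at 24 h and GI lower (−0.70 ± 0.10). The flavonoid list was called there, with a median of 0.68 (1 up and 0 down, 4 and 0 adjusted over the list alone; adjusted p = 3.71e-05, and 0.0226 with an estimated correlation), and 2 were up without replicate 2 at 28 °C and 3 h. YAB5 (0.80 ± 0.18) and IQD24 (0.75 ± 0.17) also passed in the hypocotyl, each losing the call in 7 of 12 leave-outs (0.71 to 0.82 and 0.61 to 0.75). On the negative side, ZCF37 (−0.89 ± 0.18) lost it without replicate 2 at 28 °C and 24 h (−0.82), MT1C (−0.83 ± 0.20) in 8 leave-outs (−0.85 to −0.70), GAMMA-VPE (−0.79 ± 0.15) in 3 (−0.71 to −0.66) and SKP2A (−0.72 ± 0.16) in 5 (−0.72 to −0.62). IQD24, MT1C, GAMMA-VPE and SKP2A also lost it with only the compared arrays in the fit, and MT1C with trend and robust eBayes, with the replicate block and with centring on the reference genes. Limma's moderated test gave 1289 genes with a higher and 896 with a lower effect at 24 h in the cotyledon, 257 and 190 in the root and 47 and 41 in the hypocotyl. The root count of 447 became 192 without replicate 2 at 28 °C and 3 h, and its split 360 and 96 with centring on the reference genes. The hypocotyl count of 88 became 17 and 54 without replicates 1 and 2 at 20 °C and 3 h, 52 and 22 without replicates 1 and 2 at 20 °C and 24 h, and 22 without replicate 1 at 28 °C and 3 h. It was 42, 29 and 162 without replicates 1, 2 and 3 at 28 °C and 24 h, and 49 with only the compared arrays in the fit.

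**Figure D2:**
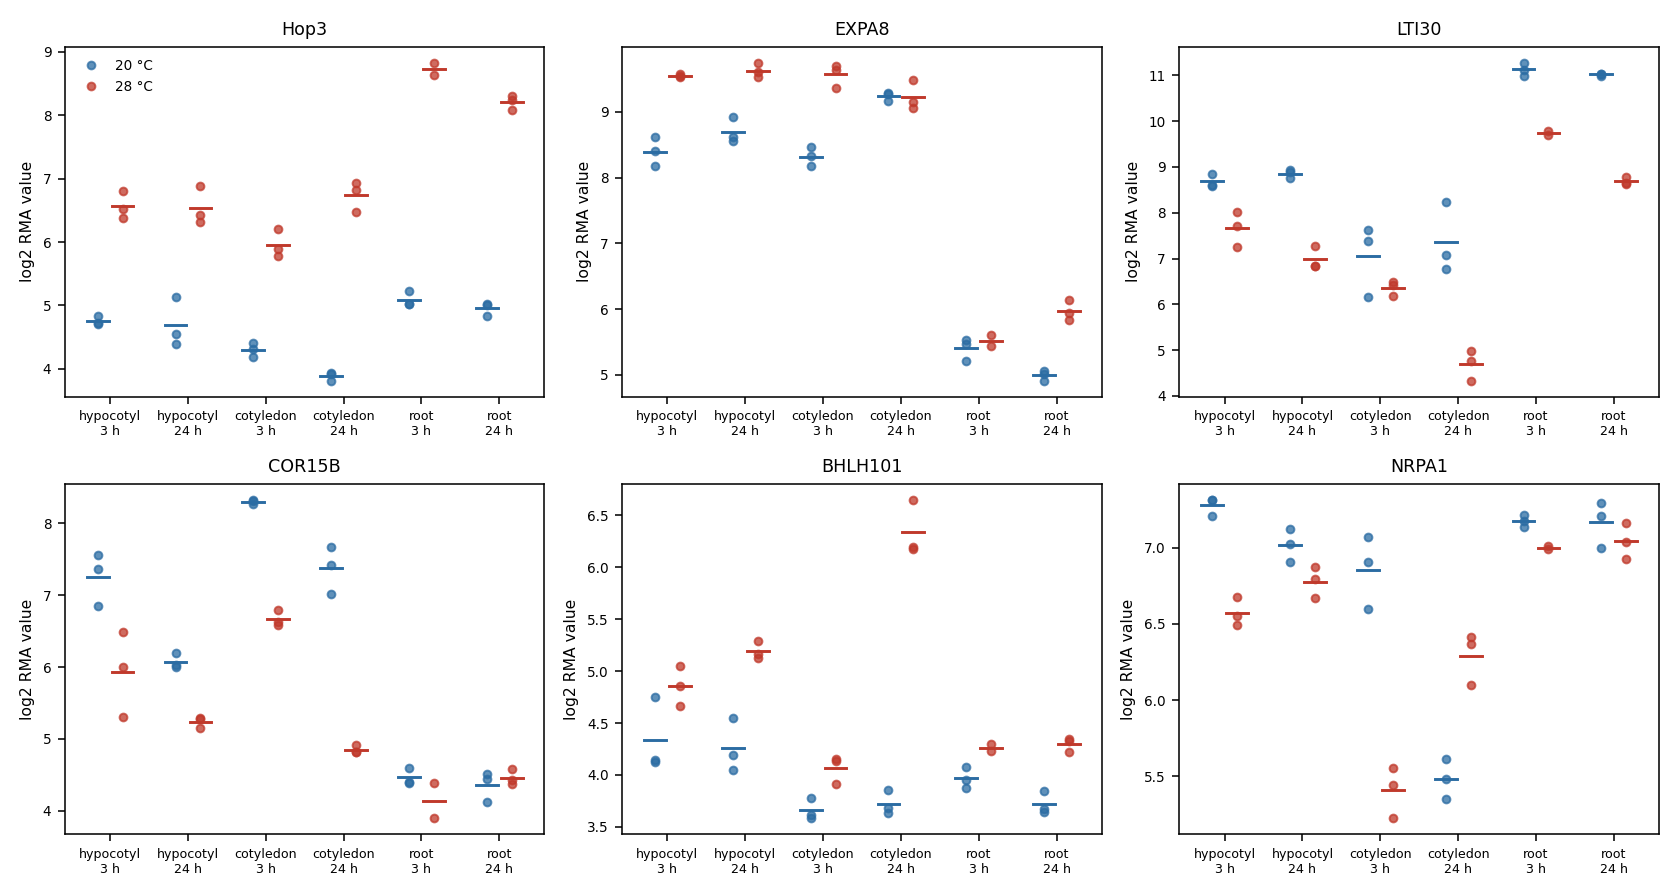
Log2 RMA values (y axis) of 6 genes in each array by organ and hours (x axis): points are arrays, bars group means, blue 20 °C and red 28 °C, and the 6 were picked for the plot after their values were seen. Hop3 was higher at 28 °C in each organ and time, LTI30 fell by 2.66 in the cotyledon at 24 h, BHLH101 rose by 2.61 in the cotyledon at 24 h, and NRPA1 in the cotyledon was lower at 28 °C at 3 h and higher at 24 h.

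The arrays kept at 20 °C show what changed between the harvest at ZT 10 of day 5 and that at ZT 7 of day 6 without a shift. In the cotyledon, HYH, a transcription factor of the light response, was higher at the later harvest by 1.61 ± 0.12, EXPB1 by 1.48 ± 0.15, LHCB4.2 by 1.15 ± 0.14 and EXPA8 by 0.92 ± 0.12. AT1G47400 (IMA1, −1.06 ± 0.11), COR15B (−0.93 ± 0.19) and ICU2 (−0.84 ± 0.14) were lower. In the hypocotyl COR15B (−1.19 ± 0.19) and SPCH, a regulator of stomatal lineage entry (−0.83 ± 0.18), were lower and HYH higher (0.90 ± 0.12). In the root AT1G47400 was lower by −0.69 ± 0.11. These members were picked from the fixed lists after their values were seen. For the cotyledon, 21 of 41 40S ribosomal protein transcripts were lower at the later harvest and 0 higher (median −0.26, camera adjusted p = 7.14e-11, lost at an adjusted p = 0.206 with an estimated correlation). In limma's moderated test 911 genes were higher and 1434 lower in the cotyledon, 144 and 115 in the hypocotyl and 22 and 34 in the root. The hypocotyl count of 259 became 468 with arrayWeights and 137 to 169 without replicate 1 or 2 of either time. The root count of 56 became 144 with arrayWeights, 31 with only the compared arrays, 88 with centring on the reference genes (14 and 74), and 30 and 32 without replicate 2 at 24 h or replicate 3 at 3 h.

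Marker genes were compared between the organs in the 20 °C arrays. All 7 photosynthesis genes were lower in root than in cotyledon and hypocotyl and lower in hypocotyl than in cotyledon. The medians were −6.14, −5.37 and −1.3 (camera adjusted p = 4.6e-07, 1.06e-08 and 0.000478, lost at adjusted p = 0.108, 0.054 and 0.216 with an estimated correlation). PSAN, a subunit of photosystem I, was lower in root than in cotyledon by −7.50 ± 0.11. The root hair expansins EXPA7 and EXPA18 were higher in root than in cotyledon by 3.13 ± 0.10 and 3.62 ± 0.12, and the root markers PYK10 and AT5G47950 by 1.62 ± 0.07 and 2.81 ± 0.11. PYK10 was also higher in hypocotyl than in cotyledon (1.04 ± 0.07). SPCH was higher in hypocotyl than in cotyledon by 1.59 ± 0.12 and FMA, a guard cell regulator, was lower (−1.26 ± 0.09). The shoot apex gene LAS was slightly higher in root (0.19 ± 0.08 against cotyledon) and CLV3 passed in no organ comparison. The cytosolic 40S transcripts were higher than in cotyledon for all 41 members in hypocotyl (median 0.91) and in root (1.22), calls lost at adjusted p = 0.0911 and 0.0982 with an estimated correlation. All 46 plastid-encoded genes were lower in root than in cotyledon (−4.01, lost at an adjusted p = 0.0982 with an estimated correlation). Counts higher and lower in limma's moderated test were 4034 and 4824 for hypocotyl against cotyledon, 5218 and 5002 for root against cotyledon and 4800 and 3269 for root against hypocotyl. Centring on the reference genes moved the median of all genes to −0.26 and −0.19 in both root comparisons, where the splits became 4165 and 7584, and 3422 and 7130.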

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

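The tests of scaling, of the harvest hour, of a single array, of the expected rise from shoot material and of the starting level were chosen only after the result was seen. The matched lists, the first shoot test and the counts over other splits were planned.

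Differences of the temperature effect between organs or times, each tested as an interaction with limma, were found for 448 genes between hypocotyl and cotyledon at 3 h and 1612 at 24 h, for 1533 and 2682 between root and cotyledon, and for 708 and 999 between root and hypocotyl. Between 24 h and 3 h, which also differ in hour of harvest and age, the effect differed for 88 genes in hypocotyl, 2185 in cotyledon and 447 in root.

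List medians whose difference passed camera of limma at the preset correlation are given next, and those that hold with an estimated correlation are the heat shock differences at 24 h of hypocotyl against cotyledon, at 3 h of root against cotyledon, at both times of root against hypocotyl and of 24 h against 3 h in cotyledon and root, and the flavonoid difference between times in hypocotyl. Hypocotyl minus cotyledon was −0.415 for the flavonoid list at 3 h, and at 24 h −0.995 for heat shock, −0.337 for 40S ribosomal proteins, 0.527 for plastid-encoded genes and 0.235 for tubulins. Root minus cotyledon at 3 h was 1.3 for heat shock, 0.463 for 40S ribosomal proteins, −0.296 for expansin and XTH, −0.104 for class III peroxidases, 0.234 for plastid-encoded genes, −0.246 for glutathione S-transferases and −0.173 for SWEET transporters. At 24 h it was −0.322 for 40S ribosomal proteins and 0.417 for plastid-encoded genes. Root minus hypocotyl at 3 h was 1.15 for heat shock, 0.374 for 40S ribosomal proteins, −0.203 for class III peroxidases, 0.183 for plastid-encoded genes, −0.141 for glutathione S-transferases, −0.101 for serine carboxypeptidase-like proteins and −0.225 for SWEET transporters, and at 24 h 0.775 for heat shock. The effect at 24 h minus that at 3 h in hypocotyl was 0.681 for flavonoid, 0.0874 for 40S ribosomal proteins, −0.242 for class III peroxidases and 0.223 for plastid-encoded genes. In cotyledon it was 0.604 for heat shock, 0.45 for flavonoid and 0.502 for 40S ribosomal proteins. In root it was 0.195 for expansin and XTH, −0.382 for heat shock, 0.368 for flavonoid, −0.268 for 40S ribosomal proteins and 0.147 for SWEET transporters.

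The 9233 probe sets without a single gene name, which the comparisons of genes do not use, also held temperature effects in limma's moderated test. In hypocotyl 1899 passed at 3 h and 1421 at 24 h, in cotyledon 2739 and 3236, and in root 1437 and 2414.

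The first pattern is the lower 40S ribosomal protein list at 3 h in hypocotyl and cotyledon and not in root, although the calls for cotyledon, root minus cotyledon, root minus hypocotyl and 24 h minus 3 h in cotyledon were lost with an estimated correlation (adjusted p = 0.0965, 0.0623, 0.064 and 0.0832). Centring on the reference genes left the list median of root minus cotyledon at 0.36 and quantile normalisation within organs at 0.467, against 0.463 as reported, which argues against scaling as the whole cause. Bright probe sets as a class did not fall as far, since 10000 lists matched on mean level had a middle median of −0.074 and a lowest of −0.366 in cotyledon, against −0.475. The hour and age of the 20 °C arrays alone do not account for the turn from 3 h to 24 h in cotyledon, since the list mean rose by 0.274 ± 0.0735 between the 28 °C arrays while it changed by −0.312 ± 0.0487 between those at 20 °C. No biological explanation was tested, and the change of the response between times was not compared between organs.

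Photosynthesis transcripts that were higher in roots at 28 °C are the second pattern, a call lost with an estimated correlation (adjusted p = 0.184 at 3 h and 0.491 at 24 h), with shoot material in the root samples as a candidate source. In cotyledon, 315 other transcripts had over 16 times the root level. Their median change was 0.065 at 3 h and 0.0233 at 24 h. The bound set was wrong, because transcripts with a smaller ratio than the list would rise less from the same share. Given the share that the list would need (0.352% and 0.307%), transcripts over 64 times higher in cotyledon would rise by a median of 0.409 and 0.368. They changed by 0.0859 (single arrays −0.122 and 0.237) and 0.0151 (−0.0254 to 0.062), which argues against shoot material as the whole cause. The expected rise takes values as proportional to transcript amount and cotyledon as only source, both untested. Of 46 plastid-encoded genes 4 rose and 0 fell at 3 h, and 5 rose and 8 fell at 24 h. At 3 h the pattern rests on replicate 2, with a list median of 0.035 without it. In that array the transcripts rose by 0.237 where 0.859 would be needed, so a partial share stays open. No biological explanation was tested.

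The stronger rise of heat shock genes in root than in cotyledon and hypocotyl at 3 h is the third pattern. A lower starting level explains at most a part, since the list mean at 20 °C was −0.332 for root minus cotyledon against a difference in response of 1.42. The list median of root minus cotyledon was 1.2 when centred on the reference genes and 1.31 with quantile normalisation within organs, which argues against scaling. The interaction itself was called by camera of limma, what in the organs gives rise to it was not tested, and root at 28 °C and 3 h has 2 arrays.

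Other splits of the same arrays were counted for each comparison of groups of 3. For 28 °C against 20 °C the 10 splits are too few for a share under 0.05, the real counts being 1954, 1291, 2985, 3805 and 2364 (hypocotyl at 3 h and 24 h, cotyledon at 3 h and 24 h, root at 24 h) and the highest of the other splits 0, 8, 14, 14 and 2. The real split called 3, 2, 1, 2 and 2 lists and the others at most 3, 2, 2, 1 and 3. With the real one, 2, 4, 7, 1 and 8 of the 10 splits reached its number. The others keep part of the temperature effect, so this does not decide on chance. Splits were also too few for the 20 °C arrays of 24 h against 3 h. Those gave 259, 2345 and 56 genes in hypocotyl, cotyledon and root against 0, 19 and 5. For the organs at 20 °C the real split alone of 100 reached 8858, 10220 and 8069 genes (highest others 6364, 8373 and 6528), which argues against chance there. Among the differences of effects, the share of splits that reached the real count was under 0.05 for root minus cotyledon at 24 h (1 of 100, 2682 against 2423) and for the time difference in cotyledon (4 of 100, 2185 against 2417). It was not under 0.05 for hypocotyl minus cotyledon at 3 h (18 of 100, 448 against 3696) and 24 h (9 of 100, 1612 against 3820), root minus hypocotyl at 24 h (7 of 100, 999 against 1581) and the time difference in hypocotyl (16 of 100, 88 against 1000). These shares do not decide on chance for any of the differences, because a split that keeps or mirrors the temperature groups of only 1 organ or time carries that temperature effect. Splits that call several times the real count point to this structure of the arrays. As a description added after these counts were seen, splits that mixed the temperatures in both parts called at most 1, 3, 1 and 2 genes for the organ differences just named (hypocotyl minus cotyledon at 3 h and 24 h, root minus cotyledon and root minus hypocotyl at 24 h) and 3 and 27 for the time differences of hypocotyl and cotyledon. Root at 28 °C and 3 h has 2 arrays, so its comparisons were not counted.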

How the results depend on the processing

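All alternatives were planned, while the counts of list members without each array were made after the results were seen. Of the counts, lists called and correlations, 447 values under other settings stayed within 1.5 times the count or within the replicate spread and 89 moved. Of 566 gene results, 127 lost the call under at least 1 setting, 1 turned direction, and of 25 called lists 18 lost it under at least 1. The gene that turned was PSBY in root at 3 h, −0.042 without replicate 2 at 28 °C and 0.938 without replicate 1, against 0.45 with both. Where no construction is named, the cause was not tested. The number of arrays limits the precision.

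With all probe sets, more of which are tested, the counts for 28 °C against 20 °C were 3876 and 2724 in hypocotyl at 3 h and 24 h, 5738 and 7041 in cotyledon and 2851 and 4798 in root. The differences gave 888 and 3062 for hypocotyl minus cotyledon, 3006 and 5144 for root minus cotyledon, 1475 and 2042 for root minus hypocotyl, and 178, 4078 and 1034 for 24 h minus 3 h in hypocotyl, cotyledon and root. The 20 °C arrays gave 682, 4444 and 170 between times, and 15716, 18075 and 14853 for hypocotyl against cotyledon, root against cotyledon and root against hypocotyl. With dim genes left out, and so fewer tested, the first and the second of these were 5883 and 6757. With only the arrays compared, which leaves fewer arrays in the fit, 242 genes passed for hypocotyl minus cotyledon at 3 h, 49 for the time difference in hypocotyl and 31 between times in root at 20 °C. ArrayWeights gave 745 for the time difference in root and 468 and 144 between times in hypocotyl and root at 20 °C, and centring on the reference genes gave 88 for the last.

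Among the 5 fixed lists, the number called became 1 with an estimated correlation in hypocotyl at 3 h (from 3) and in hypocotyl at 24 h, cotyledon at 24 h and root at 3 h and 24 h (from 2 each). It became 1 with fry in hypocotyl at 24 h and 2 in cotyledon at 3 h (from 1). With dim genes left out it was 1 in hypocotyl, cotyledon and root at 24 h, with centring on the reference genes 1 in cotyledon and root at 24 h, and with quantile normalisation within organs 1 in cotyledon at 24 h. Correlations across genes with Spearman's rho were 0.502 and 0.382 for hypocotyl and cotyledon at 3 h and 24 h, 0.274 and 0.186 for root and cotyledon, and 0.292 and 0.298 for root and hypocotyl. Over called genes only, r was 0.744 and 0.558 for hypocotyl and cotyledon, 0.39 for root and cotyledon at 3 h, and 0.476 and 0.418 for root and hypocotyl. With dim genes left out it was 0.701 and 0.528 for hypocotyl and cotyledon, 0.374 for root and cotyledon at 3 h and 0.451 for root and hypocotyl at 3 h.

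Leaving out 1 array at a time gave ranges of 1183 to 1719 genes in hypocotyl at 3 h and 746 to 1306 at 24 h, 2530 to 2735 and 3229 to 3508 in cotyledon, and 731 to 1227 and 1839 to 2018 in root. For the differences the ranges were 312 to 458 and 1370 to 1530 (hypocotyl minus cotyledon), 1031 to 1504 and 2258 to 2561 (root minus cotyledon), 394 to 699 and 752 to 1056 (root minus hypocotyl), and 17 to 162, 1931 to 2183 and 192 to 410 for the time differences of hypocotyl, cotyledon and root. At 20 °C they were 137 to 279, 1885 to 2176 and 30 to 60 between times, and 8359 to 8680, 9891 to 10098 and 7864 to 7928 between organs. Lists called ranged from 1 to 2 in cotyledon at 24 h, 2 to 3 in root at 3 h and 1 to 3 in root at 24 h. Correlations ranged from 0.604 to 0.639 and 0.463 to 0.491 for hypocotyl and cotyledon, 0.313 to 0.342 and 0.234 to 0.27 for root and cotyledon, and 0.342 to 0.398 and 0.311 to 0.363 for root and hypocotyl. The arrays that moved the gene count of a comparison by more than 1.5 times are named with the results.

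The replicate numbers do not pair the arrays of both temperatures. Over 17 pairs of equal number, organ and time, the deviations from the group means correlated across genes at −0.201 to 0.166, above 0.1 in 3. Such weak correlations do not exclude a pairing. With the replicate number as a block, 1914 and 1301 genes passed in hypocotyl, 2954 and 3766 in cotyledon and 1352 and 2335 in root. The time difference in hypocotyl gave 73 genes with the block, and 3 lists were called in root at 3 h.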

Other observations

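Families that camera of limma did not call in 28 °C against 20 °C still had members that changed. Among 14 glutathione S-transferases, GSTU18 rose in hypocotyl (0.83 ± 0.10 at 3 h, 0.69 ± 0.10 at 24 h), cotyledon (1.06 ± 0.10 and 0.87 ± 0.10) and root at 24 h (0.73 ± 0.10), while GSTU25 fell in hypocotyl and root. GSTU18 and, below, AT1G49570 were chosen after their values were seen. In cotyledon at 24 h 4 of this family rose and 2 fell (adjusted p = 0.405), and in root at 3 h 1 rose and 5 fell (adjusted p = 0.146). Of 29 serine carboxypeptidase-like genes 8 fell and 3 rose in root at 24 h (adjusted p = 0.496), of 22 TBL genes 6 rose and 2 fell there (adjusted p = 0.496), and of 20 beta-glucosidases 4 rose and 1 fell (adjusted p = 0.653). Of 19 CYP71B cytochromes 5 fell and 1 rose in cotyledon at 24 h (adjusted p = 0.281). Among the class III peroxidases in root at 24 h, where 9 rose and 11 fell (adjusted p = 0.761), AT1G49570 changed by −2.0 ± 0.13. Leaving out single arrays moved some of these counts, up and down. In root at 3 h the glutathione S-transferases had 0 and 2 without replicate 2 and 0 and 4 without replicate 1 at 28 °C, and 0 and 4, and 0 and 5, without replicates 2 and 3 at 20 °C. In root at 24 h TBL genes had 3 and 2, and 5 and 1, without replicates 1 and 2 at 28 °C, and beta-glucosidases 4 and 0 without replicate 2 at 28 °C or replicate 1 at 20 °C and 2 and 1 without replicate 3 at 20 °C. CYP71B cytochromes in cotyledon at 24 h had 2 and 4 without replicate 1 and 1 and 2 without replicate 2 at 20 °C, and 2 and 5, and 1 and 2, without replicates 1 and 3 at 28 °C.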
